A study of Rattus norvegicus with 9 samples.

How the data were processed

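Total RNA from the cortex of 9 non-irradiated Sprague-Dawley rats aged 60 days (3 females, 6 males) had been amplified to biotin-labelled cRNA and hybridised to Illumina rat bead arrays, per the labels' protocols. The protocols state that cortex and hippocampus were separated and that cortex alone was used. Each sample's own table held one linear probe intensity per probe for 22517 probes, as the authors deposited it. From the values, these intensities were neither normalized between arrays nor background-subtracted to 0. The scanner software and the probe summary are not given in the sources used here. The authors also deposited a table of the whole series with log2 values for 15912 probes. These correlated at 0.99996 or above, per array, with the quantile-normalized log2 of the single tables, and their medians were 6.125 to 6.127, so scale (log2) and quantile normalization were taken from the values; no centring of genes was seen. The 6605 probes outside it were dimmer (median log2 intensity 5.32 against 6.13). The table was used as an alternative, and only its columns for these samples were used.

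The intensities were background-corrected with normexp (offset 50) and quantile-normalized between arrays after log2 transformation, in limma 3.58.1 under R 4.3.3. The tables carried no detection p-values, so the fallback fixed in advance was used: a probe was called detected where it exceeded the 25th percentile of its array, and the 18531 probes detected on at least 3 arrays were tested. With the offset, fold changes of dim probes are understated. No pair of arrays had identical values; 571 probes had the same value as another probe on every array, and each probe was kept on its own. Gene symbols came from the platform annotation supplied with the data: 10687 probes had a symbol and 11830 had none, and the latter are given by probe ID. Of the named probes, 10662 were updated through their gene identifiers in a RefSeq table of assembly GRCr8, which was used for names only, so no coordinates are given.

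Animals were grouped by the sex in the labels and numbered within sex in the order of the records; the numbers are names only. The main comparison was male minus female with limma (lmFit and eBayes), adjusted by Benjamini-Hochberg over all tested probes. The number in each title (3 numbers, each with 1 female and 2 males) was tested with limma's F test with sex as a covariate, as a possible batch of unstated meaning. The study design names a threshold of p under 0.001 without its test, and counts at that unadjusted threshold are given too. In all, 29 gene lists (cell types, brain regions, activity, stress, channels and receptors, migration, DNA damage and housekeeping groups) were fixed before the data were examined, as were the tests, most of the alternatives and the rule for named genes. For lists, each gene was represented by its probe with the highest mean, over 10327 genes, and the 28 lists with at least 5 genes were tested. Lists were compared between sexes by camera with a preset correlation of 0.01, with camera's estimated correlation and fry beside it. Coordinated variation was the mean pairwise Pearson correlation of a list over the 9 animals, on residuals from the sex means. It was compared one-sided with 10000 random lists of genes matched on decile of mean level, adjusted over 28 lists. This random-list test draws genes and does not shuffle animals. The labels give no replicate numbers that pair animals, so no paired test was made.

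The named genes were the 20 probes with the smallest p between the sexes, all measured X escape and Y-linked genes, the 10 probes with the smallest p across title numbers, the 20 probes with the largest SD within sex among probes detected on all 9 arrays, and up to 4 members per list by smallest p or largest SD. ILMN_1650254, Slco1a5, Mog and Mal in the report, and genes of the closing section, among them those picked for male 5, fall outside this rule and were chosen after their values were seen. Alternatives were another background floor (64), no normalization, scaling to the 75th percentile, no filter or detection on all arrays, the deposited series table, array weights, title number as a block, an intensity trend, a per-probe test, other set tests, Spearman correlation, and leaving out each animal. Added after seeing the data were leaving out the 3 dimmest arrays and leaving out males 3 and 5.

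The procedures were tested on simulated data: independent normal noise with the mean and within-sex SD of each probe, and 200 of 18531 probes shifted by known amounts. The shifted probes were drawn from those detected on every array. Between the sexes, limma called 22%, 70%, 98% and 98% of probes shifted by 0.25, 0.5, 1 and 2 log2 units, and 10 of 18331 unshifted probes. Across title numbers it called 4%, 56%, 92% and 98%, and 12 unshifted probes. Camera, fry and the coordination test each called the 1 altered list and 0 of the other 27; because the noise was independent between genes, this does not test camera's preset correlation. Irradiated animals of the study were not analysed here. Figures were drawn with matplotlib 3.10.9.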

Results

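Gene expression was measured in the cerebral cortex of 9 Sprague-Dawley rats, 3 females and 6 males, at 60 days of age. All were non-irradiated animals, the control arm of a study of cortical dysplasia in the offspring of irradiated rats; the irradiated arm was not analysed here. One Illumina rat bead array was hybridised per animal, and the labels describe each sample as the tissue of one animal. Each array reported 22517 probes. Mean array intensity ranged from 183.6 in male 4 to 238.8 in male 5, and the 3 dimmest arrays (male 4, female 2 and male 2) lay at 183.6 to 185.4 while the other 6 lay at 212.2 or above. Pairwise correlations between arrays on the log2 scale were 0.982 to 0.995. The number of arrays limits the precision: the median SD of log2 intensity between animals of one sex was 0.11 over the 13002 probes detected on every array. The limma p-values of single probes below measure the spread between these samples. Those of camera and of the coordination test compare the genes of a list with other genes.

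The sexes were compared because sex was the one labelled property in which the animals differed. The lowest p-values among named genes belonged to transcripts with small differences. Aldh5a1, which encodes succinic semialdehyde dehydrogenase of GABA breakdown, averaged 7.36 ± 0.05 (SD, n = 3) in females and 7.14 ± 0.07 (SD, n = 6) in males, a log2 difference (male minus female) of -0.22 ± 0.05 (SE). Spred1, an inhibitor of Ras to MAP kinase signalling, averaged 8.49 ± 0.10 in females and 8.23 ± 0.08 in males. Chordc1, an Hsp90 co-chaperone, averaged 8.98 ± 0.15 and 8.64 ± 0.12, and Psmd5, a proteasome assembly chaperone, averaged 7.47 ± 0.14 and 6.94 ± 0.27. Higher male averages were measured for Tor3a, a torsin family ATPase (6.27 ± 0.02 in females and 6.54 ± 0.13 in males), for Maob, the X-linked monoamine oxidase B (8.28 ± 0.09 and 8.50 ± 0.08), and for Flna, the X-linked actin cross-linker filamin A (a log2 difference of 0.20 ± 0.06, SE).

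The remaining named genes among the 20 probes with the smallest p were Rnf26 (log2 difference -0.22 ± 0.06, SE), H2ap (-0.17 ± 0.05), Cep76 (-0.19 ± 0.05), Slc35f2 (-0.15 ± 0.04), Cacnb2 (-0.15 ± 0.04), Tlcd4 (-0.17 ± 0.05) and Lynx1 (-0.21 ± 0.06). A further 6 of the 20 had no gene name here: ILMN_1650944 (0.37 ± 0.08), ILMN_1369703 (0.22 ± 0.06), ILMN_1360211 (0.17 ± 0.05), ILMN_1367429 (0.16 ± 0.05), ILMN_1364369 (-0.17 ± 0.04) and ILMN_1375617 (-0.25 ± 0.07). The last of these carried the same value as the Bag3 probe on every array. Males and females did not overlap for ILMN_1650944, whose female values were 7.13 to 7.27 and whose male values were 7.45 to 7.77. That is not particular to this probe: of the 20, only Chordc1 had any overlap, and the choice by the smallest p favours such separation. In each of the 3 title numbers described below, the difference of each of these 20 probes had the same sign, which their choice by the smallest p largely fixed.

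None of these differences passed the adjusted test. With limma, 0 of 18531 tested probes were under an adjusted p of 0.05, and the smallest adjusted p was 0.9999. At the unadjusted threshold of 0.001 that the study design names, 1 probe was called, ILMN_1650944. This count was 0 without female 1, female 3 or male 5, 2 without male 1, 5 without male 3, 6 without male 2 and 7 without female 2. At an unadjusted p of 0.05, limma called 439 probes, 220 higher in males and 219 higher in females, where 926.6 would be expected with no difference; the count was 288 without female 1 and 720 without female 2. A per-probe test without variance moderation called 0 probes after adjustment and 578 at an unadjusted p of 0.05. In simulated data with the same design, limma called 70% of probes shifted by 0.5 log2 units and 98% of those shifted by 1. The shifted probes were all detected on every array, and the noise was independent between probes. These shares therefore do not give the power of the real comparison.

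X-linked genes that escape inactivation in rodents showed small differences. Eif2s3, a translation initiation factor subunit, averaged 6.70 ± 0.16 (SD, n = 3) in females and 6.47 ± 0.11 (SD, n = 6) in males, a log2 difference of -0.23 ± 0.08 (SE). Pbdc1 differed by -0.14 ± 0.07, Usp9x by -0.03 ± 0.05, Ddx3x by -0.0012 ± 0.057 and Mid1 by 0.06 ± 0.05. Pbdc1 was the brightest, at 8.81 in females and 8.67 in males. Usp9x averaged 6.90 and 6.87, Ddx3x 6.20 in both sexes and Mid1 5.95 and 6.01. The offset understates fold changes of such dim probes, that of Eif2s3 included. Their small values therefore do not show that the sexes are equal. The 5 measured genes together did not pass the set test (camera adjusted p = 0.15, and 0.40 with an estimated correlation), and 0 of them passed when adjusted over the list alone. The other 5 genes of this list, and all 11 genes of the Y-linked list, had no tested probe under their names here. The sex labels could therefore not be checked against Y-linked expression, and every male minus female value rests on the labels.

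Activity and stress genes averaged lower in males. Of 35 measured immediate early genes, 30 had the lower male average, with a median log2 difference of -0.12 (camera adjusted p = 3.1e-06; adjusted p = 0.22 with an estimated correlation). Among them, Arc, a synaptic activity marker, differed by -0.72 ± 0.29 (SE); the female and male averages were, for Fos, 8.04 ± 0.36 and 7.70 ± 0.18 (SD, n = 3 and n = 6), for Ier5 7.38 ± 0.14 and 7.03 ± 0.27, and for Dusp6, a phosphatase of ERK, 9.30 ± 0.04 and 9.07 ± 0.16. Heat shock protein genes were lower in males in 10 of 12, with a median of -0.15 (adjusted p = 0.00033; adjusted p = 0.22 with an estimated correlation). Chordc1 and the co-chaperone Bag3 (7.23 ± 0.14 and 6.98 ± 0.09) passed when adjusted over the list alone (smallest adjusted p = 0.028, limma), while 0 passed over all probes; Dnajb1 differed by -0.15 ± 0.06 (SE) and Dnaja1 by -0.16 ± 0.07. The female averages of both lists were carried by females 1 and 3: their immediate early scores, the mean log2 deviation of the genes from the median of all animals, were 0.22 and 0.10 against -0.02 in female 2, and their heat shock scores were 0.22 and 0.17 against -0.14. Without female 1 the medians shrank to -0.05 for immediate early genes and -0.06 for heat shock genes, and without male 1 the immediate early median was -0.08; without female 2 the heat shock median was -0.24. Both lists passed camera's adjusted threshold without each animal in turn.

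Glucocorticoid-responsive genes had a median male minus female difference of -0.10, with 14 of 20 lower in males (camera adjusted p = 0.032; adjusted p = 0.46 with an estimated correlation). Its members with the smallest p were Tsc22d3 (-0.31 ± 0.14, SE), Fkbp5 (-0.35 ± 0.16), Klf9 (-0.24 ± 0.13) and Cdkn1a (-0.11 ± 0.06). Circadian clock genes were lower in males in 11 of 15 (median -0.07, adjusted p = 0.043; adjusted p = 0.37 with an estimated correlation). These included Bhlhe40 (-0.44 ± 0.13), Bmal1 (-0.18 ± 0.07) and Nfil3 (-0.30 ± 0.15), while Per3 differed by 0.10 ± 0.05. Synaptic vesicle genes were lower in males in 16 of 24 (median -0.07, adjusted p = 0.039; adjusted p = 0.22 with an estimated correlation), with Vamp1 at -0.35 ± 0.19, Snap25 at -0.27 ± 0.14, Cplx1 at -0.19 ± 0.14 and Syt1 at -0.09 ± 0.06. These 3 calls were lost when single animals were left out. The glucocorticoid call was lost without female 3 (median -0.04, camera adjusted p = 0.50), male 1 (-0.02) or male 6 (-0.04), and also without male 2, where the median was -0.11. The circadian call was lost without female 2 or males 1, 5 or 6, with medians of -0.08 to -0.06, about as large as with all animals. The synaptic vesicle call was lost without female 1 (median -0.03), female 2 (-0.04) or male 3 (-0.05), and without female 3 or males 2 or 4, where the median of -0.08 was not smaller.

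Meningeal, choroid plexus, endothelial and microglia markers had higher male averages, which for several of these lists rested on 1 or 2 animals. Of 21 meningeal fibroblast markers, 19 had the higher male average, with a median difference of 0.20 (camera adjusted p = 1.1e-05; adjusted p = 0.40 with an estimated correlation). The collagens Col3a1 (0.24 ± 0.09, SE) and Col1a2 (0.59 ± 0.36), the growth factor binding protein Igfbp2 (0.39 ± 0.19) and the matrix protein Mgp (0.26 ± 0.15) had the smallest p. The low female average came from female 2, whose score was -0.41, against 0.04 and -0.03 in females 1 and 3 and -0.20 to 0.37 in males; without female 2 the median was 0.07 (camera adjusted p = 0.24), and without male 4 or male 5 it was 0.13. Choroid plexus markers were higher in males in 14 of 17 (median 0.11, adjusted p = 0.0052; adjusted p = 0.46 with an estimated correlation), with Col8a1 at 0.19 ± 0.08, Igf2 at 0.59 ± 0.37 and Abca4 at 0.10 ± 0.07. Male 3 (score 0.92) and male 2 (0.31) stood apart, while the other 4 males (-0.06 to -0.01) lay within the female range of -0.12 to 0.04, and the call was lost without male 3 (median 0.04, camera adjusted p = 0.20) or without female 2 (median 0.10, about as large, adjusted p = 0.10). Endothelial and pericyte markers were higher in 10 of 14 (median 0.06, adjusted p = 0.028; adjusted p = 0.22 with an estimated correlation), among them Slc38a5 (0.20 ± 0.09), Itm2a (0.34 ± 0.16), Vtn (0.20 ± 0.09) and Tie1 (0.11 ± 0.06); this call was lost without female 2 (median 0.04, camera adjusted p = 0.18). Microglia and macrophage markers were higher in 13 of 21 (median 0.04, adjusted p = 0.033; adjusted p = 0.46 with an estimated correlation), led by Aif1 (0.33 ± 0.10), the complement gene C1qa (0.21 ± 0.08), Trem2 (0.27 ± 0.14) and Fcgr3a (0.09 ± 0.06), and this call was lost without female 2 or males 2, 4 or 5 (medians -0.0017, 0.05, 0.02 and 0.03). Among the blood markers, which did not pass (camera adjusted p = 0.17), Hba-a1 differed by 0.54 ± 0.19 and Hbb by 0.53 ± 0.27, and female 2 had the lowest blood score, -0.27.

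Cytosolic ribosomal protein genes were higher in males in 48 of 60, with a median difference of 0.06 (camera adjusted p = 1.1e-05; adjusted p = 0.22 with an estimated correlation). Rps18 differed by 0.15 ± 0.05 (SE), Rps15 by 0.17 ± 0.07, Rpl39 by 0.18 ± 0.07 and Rps27 by 0.15 ± 0.06. Without female 2 the call was lost (median 0.02, camera adjusted p = 0.10), and without male 2 or male 5 the median was 0.10 or 0.04. In all, camera with a preset correlation of 0.01 called 10 of 28 lists, 5 higher and 5 lower in males. With an estimated correlation it called 0, with 5 lists at an unadjusted p of 0.05, and fry also called 0, with 1 list at an unadjusted p of 0.05 and a smallest adjusted p of 0.38. The mean pairwise correlation on residuals from the sex means was 0.53 for choroid plexus, 0.44 for meningeal and 0.21 for glucocorticoid-responsive genes. It was 0.18 for microglia, 0.14 for immediate early, 0.11 for heat shock, 0.07 for ribosomal and 0.06 for circadian genes. All of these exceed the preset 0.01. For heat shock and circadian genes, however, they lay under the 95th percentile of random lists (0.12 and 0.09), so a true excess is not established there. For the other lists named here the preset p-values are too small. The synaptic vesicle and endothelial lists had mean correlations of 0.006 and 0.005. Apart from Chordc1 and Bag3, 0 members of any list passed when adjusted over the list alone. Without female 2, camera called 3 lists (immediate early, heat shock and glucocorticoid-responsive genes), and the median of the microglia markers turned to -0.0017.

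**Figure D1:**
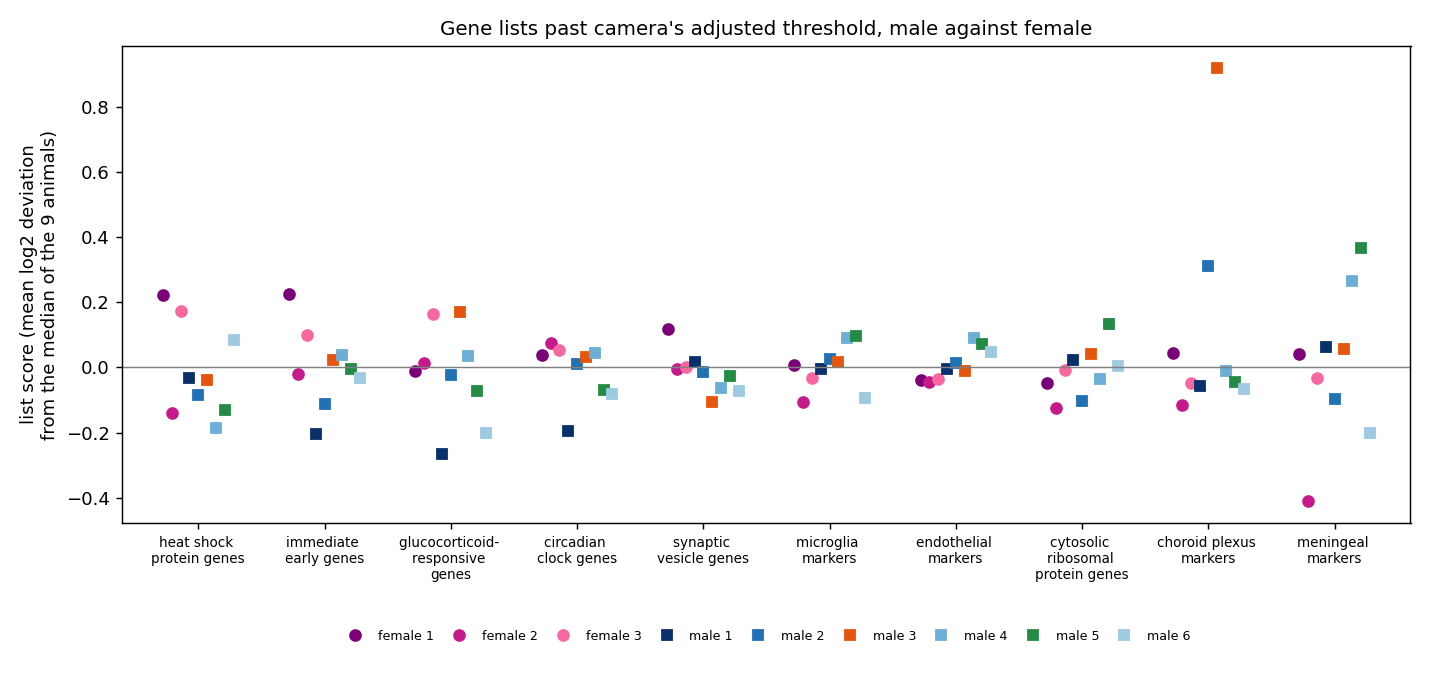
Scores of the 10 gene lists that passed camera's adjusted threshold with the preset correlation, one point per animal (circles females, squares males); the vertical axis is the mean log2 deviation of the genes of a list from their median over the 9 animals. Male and female points overlap in each list except the endothelial markers, where the 3 females lie at -0.04 and the males between -0.01 and 0.09; male 3 stands at 0.92 for choroid plexus markers and female 2 at -0.41 for meningeal markers.

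The other 18 tested lists did not pass camera's adjusted threshold between the sexes, with adjusted p from 0.069 to 0.97. They held markers of excitatory neurons, GABAergic interneurons, astrocytes, myelin, oligodendrocyte precursors, blood, hippocampus, striatum and thalamus. They also held genes of sex steroids and neuropeptides, X escape, GABA receptors, glutamate receptors, sodium and potassium channels, neuronal migration, p53 targets, the mitochondrial respiratory chain and the interferon response. For the thalamic and mitochondrial lists the median difference (-0.02 and -0.006) was opposite in sign to the direction of the test.

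The sample titles carry one of 3 numbers whose meaning the labels do not give, and each number covers 1 female and 2 males; averages below are given for the lowest, the middle and the highest number in that order. The lowest p-values across these numbers belonged to Lrrc8a, a volume-regulated anion channel subunit, which averaged 6.68 ± 0.16 (SD, n = 3), 6.24 ± 0.05 and 6.90 ± 0.07. Adgrb2, an adhesion receptor, averaged 9.19 ± 0.15, 9.07 ± 0.22 and 9.80 ± 0.20. Fads1, a fatty acid desaturase, averaged 9.15 ± 0.08, 9.34 ± 0.04 and 8.94 ± 0.07, and Sod3, the extracellular superoxide dismutase, 7.62 ± 0.06, 7.90 ± 0.11 and 7.47 ± 0.02. Neto2, a kainate receptor auxiliary subunit, averaged 7.40 ± 0.07, 6.99 ± 0.14 and 6.90 ± 0.03, and Ccdc77 averaged 6.27 ± 0.13, 5.88 ± 0.02 and 6.38 ± 0.07. The unnamed probes ILMN_1367750 (7.47, 7.27 and 7.86), ILMN_1366355 (10.85, 11.18 and 11.29), ILMN_1349312 (7.60, 8.09 and 7.60) and ILMN_1360839 (highest for the middle number, at 7.53) completed the 10 probes with the smallest p.

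With sex as a covariate, limma called 0 of 18531 probes across the title numbers at an adjusted p of 0.05 (smallest adjusted p = 0.29, shared by these 10 probes), 58 at an unadjusted p of 0.001 and 1772 at 0.05. Without male 4, limma called 1 probe, ILMN_1366937, at an adjusted p of 0.022. Without the 3 dimmest arrays, a setting chosen after the data were seen, it called the choroid plexus genes Sostdc1 and F5 and the transporter Slco1a5, each at an adjusted p of 0.031; male 3 was then the only animal of the middle number, and its spread was assumed to equal that of the others.

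Variation among control animals was examined because it sets, together with the number of animals, how small an effect of irradiation could be detected. Myelin and oligodendrocyte markers varied together most tightly: the mean pairwise correlation of 21 genes over the 9 animals, after removal of the sex means, was 0.58, against a 95th percentile of 0.06 for random lists matched on level. Male 5 had the lowest values of major myelin transcripts. In that animal, Mbp (myelin basic protein) was at 9.13 against a median of 10.55 in the other animals, Mobp at 9.20 against 10.67, Mog at 9.22 against 10.38 and Mal at 10.57 against 11.82. Opalin, the list member with the largest SD within sex (0.67), ranged from 6.68 in male 5 to 8.82 in male 2, and Ermn (SD 0.56) from 8.03 to 9.70 in the same animals.

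Choroid plexus markers were the second most coordinated list (17 genes, mean correlation 0.53, random 95th percentile 0.06). Ttr, the transthyretin gene that choroid plexus epithelium expresses at very high level, was at 12.72 in male 3 and 10.45 in male 2, and at 6.48 to 8.11 in the other 7 animals. Sostdc1 was at 8.53 in male 3, 6.97 in male 2 and 5.82 to 6.02 elsewhere, and F5, coagulation factor V, at 7.99, 6.65 and 6.03 to 6.17. Igf2, which meningeal cells also express, ranged from 8.94 in female 2 to 10.94 in male 3.

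**Figure D2:**
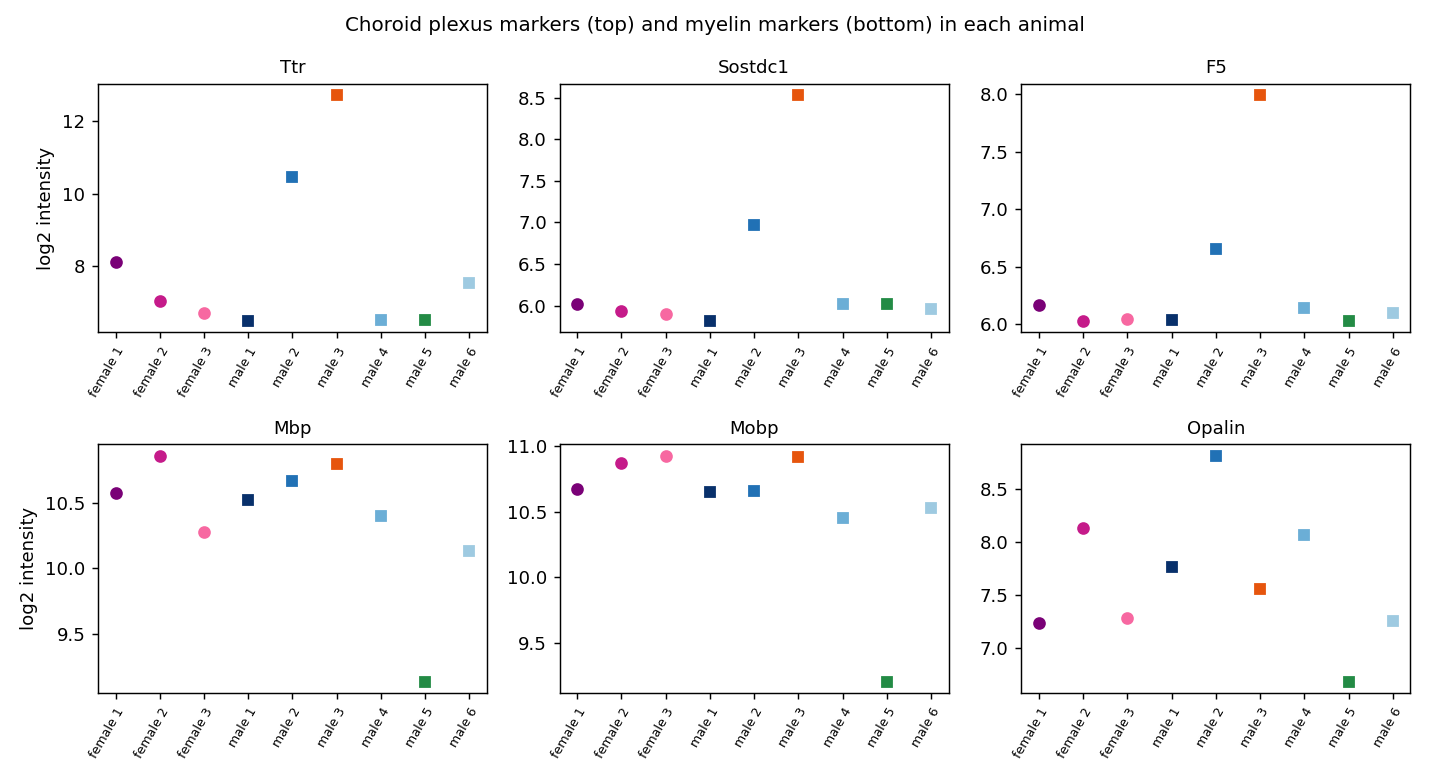
Log2 intensity of 3 choroid plexus markers (Ttr, Sostdc1 and F5) and 3 myelin markers (Mbp, Mobp and Opalin) in each of the 9 animals, one point per animal and one panel per probe with its own vertical axis. Ttr stands at 12.72 in male 3 and 10.45 in male 2, and male 5 has the lowest point of each myelin marker.

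Meningeal fibroblast markers (21 genes) had a mean correlation of 0.44 (random 95th percentile 0.06). Col1a2 ranged from 7.63 in female 2 to 9.78 in male 5, Ogn from 6.70 in female 2 to 8.60 in male 4, and Ptgds, the lipocalin-type prostaglandin D synthase, from 11.79 in female 2 to 13.44 in male 5. Striatal markers (18 genes) had a mean correlation of 0.26. Adora2a, an adenosine receptor, was at 9.17 in male 2, 8.92 in female 2 and 8.77 in male 5, and at 7.03 to 7.91 in the other 6. Rgs9 was at 8.54, 8.36 and 8.27 in the same 3 animals and at 7.40 to 7.87 elsewhere. Penk reached 10.12 in male 5 and 9.73 in male 2, while Scn4b, also in this list, was lowest in male 5, at 7.11.

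Glucocorticoid-responsive genes (20 genes, mean correlation 0.21) varied with Sgk1, a kinase induced by corticosteroids, at 9.55 in male 6, 9.70 in male 1, 10.32 in male 5 and 10.46 in female 1, and at 11.26 to 11.60 in the other 5 animals. Per1 was lowest in male 1, at 7.33, and 8.09 to 8.66 elsewhere; Errfi1 ranged from 7.52 to 8.42 and Nfkbia from 8.41 to 9.42. Immediate early genes (35 genes, mean correlation 0.14) had their highest score in female 1 (0.22) and their lowest in male 1 (-0.20). Arc was at 10.37 in female 1 and at 8.67 in male 1, Dusp1 ranged from 9.89 in male 5 to 11.09 in male 4, and Nr4a2 from 6.74 in male 2 to 8.14 in male 5.

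Microglia and macrophage markers (21 genes) had a mean correlation of 0.18, with C1qc at 7.19 in female 2 and 7.95 in male 5 and Fcer1g at 8.53 and 9.39; Trem2 ranged from 7.83 to 8.51 and Ctss from 10.33 to 11.06. Mitochondrial respiratory chain genes (58 genes) had a mean correlation of 0.17, and their 3 lowest scores (-0.10, -0.10 and -0.07) fell on the 3 dimmest arrays. Ndufb3 was at 10.48, 10.32 and 10.23 in male 2, male 4 and female 2 and at 10.59 to 10.89 elsewhere, and Ndufb6 at 9.66, 9.59 and 9.62 against 9.95 to 10.31. Ndufa10 was highest in female 2 (11.41) and male 4 (11.06), and Cox6a2 ranged from 6.99 in male 5 to 7.91 in male 1. Ribosomal protein genes (60 genes) had a mean correlation of 0.07, with Rpl23 at 9.46, 9.53 and 9.29 on the same 3 arrays and at 10.26 to 10.56 on the others, and Rps12 at 8.29, 8.53 and 8.27 against 8.82 to 9.46. Rps9 was at 9.20 to 9.94 in female 2, male 3 and male 5 and at 5.91 to 6.28 in the rest, and Rpl30 ranged from 9.99 to 11.09. Interferon and MHC class I genes (27 genes) had a mean correlation of 0.11, with RT1-A2 at 6.60 to 7.52, RT1-T24-4 at 6.09 to 7.02, Ifi27 at 8.95 to 9.96 and RT1-S3 at 6.53 to 7.25.

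These 10 of 28 lists passed the random-list test, with 10000 random lists, at an adjusted p of 0.05. The adjusted p was 0.00047 for the myelin, choroid plexus, meningeal, striatal, mitochondrial and immediate early lists. Their unadjusted p of 0.0001 was the smallest the test could give. The adjusted p was 0.0016 for glucocorticoid-responsive genes, 0.0021 for microglia and 0.0031 for ribosomal and for interferon and MHC genes. Without normalization between arrays 4 lists passed.

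**Figure D3:**
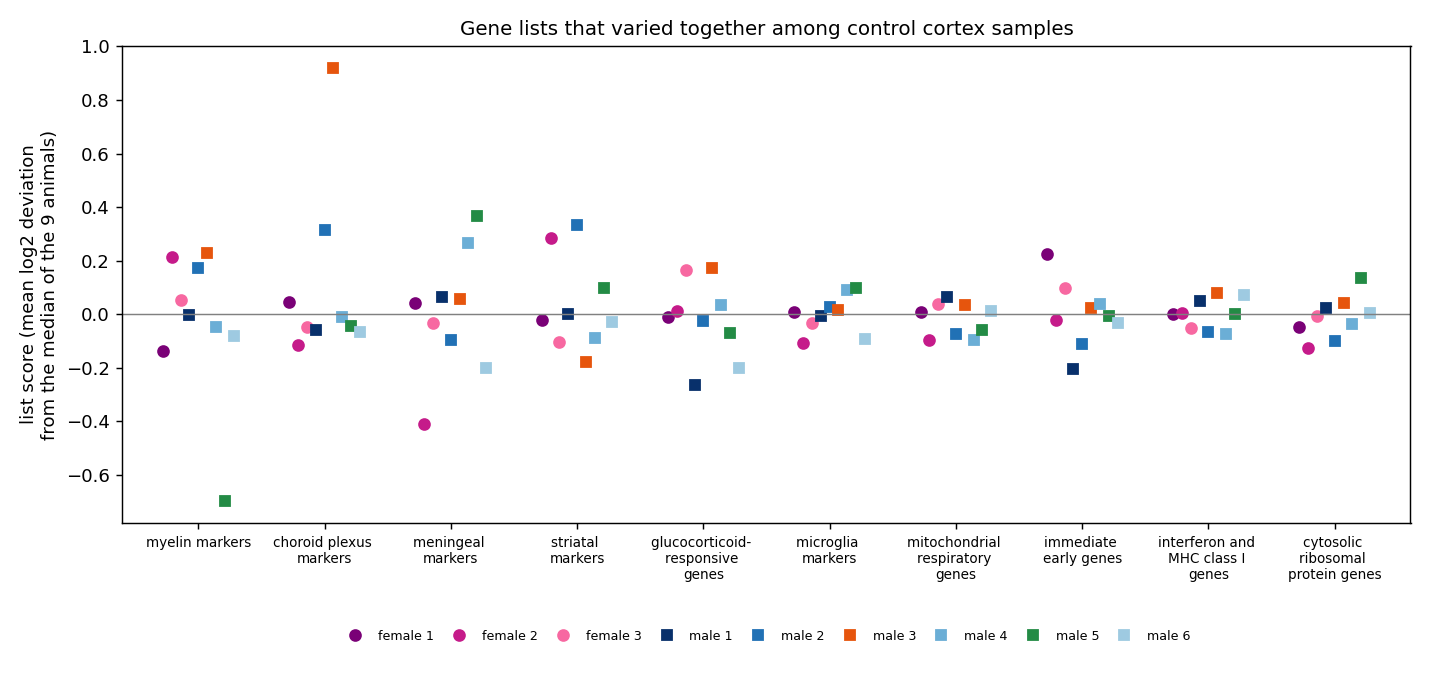
Scores of the 10 gene lists that varied together among the animals, one point per animal (circles females, squares males), ordered by mean pairwise correlation; the vertical axis is the mean log2 deviation of the genes of a list from their median over the 9 animals. Male 5 lies at -0.70 for myelin, male 3 at 0.92 for choroid plexus and female 2 at -0.41 for meningeal markers.

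Gene groups tied to cortical dysplasia and irradiation did not vary together beyond random lists. The 32 neuronal migration and malformation genes had a median SD within sex of 0.15 and a mean correlation of 0.004 (adjusted p = 0.52, random-list test). Pafah1b1, the lissencephaly gene, had an SD of 0.33 around 8.25 in both sexes, and Kif5c, Nrp1 and Itgb1 had SDs of 0.31, 0.27 and 0.25. The 16 p53 target genes had a median SD of 0.13 (adjusted p = 0.71, random-list test), with Ccng1 at 0.25, Ei24 at 0.22, Gadd45a at 0.22 and Sesn1 at 0.20. The 11 GABA receptor and chloride transport genes, which include the GABA-B subunits Gabbr1 and Gabbr2, had a median SD of 0.24 (adjusted p = 0.71, random-list test), with Gabrb2 at 0.27 and Gabra4, Gabrd and Gabbr2 at 0.26. The 22 glutamate receptor genes had a median SD of 0.11 (adjusted p = 0.26, random-list test), with Grin1 at 0.27 and Gria2 at 0.24. The remaining 14 lists that did not pass had an adjusted p in the random-list test from 0.052 (astrocyte markers, mean correlation 0.12) to 0.94 (sex steroid and neuropeptide genes).

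Single probes with the largest spread were taken from those detected on every array. After Ttr (SD within sex 2.25), they were the unnamed ILMN_1365113, Sorbs2, an actin-associated adaptor (1.55), ILMN_1374322 (1.15), Plekhh1 (1.06) and the mitochondrial ribosomal protein gene Mrpl18 (1.00). ILMN_1365113 was at 10.16 to 10.46 in female 2, male 3 and male 5 and at 6.43 to 6.77 in the other 6. Sorbs2 was at 6.16 in female 2 and 6.29 in male 3 and at 8.75 to 9.82 elsewhere. Mrpl18 was at 9.08 in male 5 and at 5.97 to 6.36 in the others. Washc3, a WASH complex subunit (SD 0.81), was at 7.82 and 7.86 in males 1 and 5 and at 5.93 to 6.04 elsewhere, and Car3, a carbonic anhydrase (0.96), was at 8.16, 8.61 and 7.96 in males 1, 5 and 6 and at 6.04 to 6.31 elsewhere.

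The rest of the 20 were ILMN_1351707 (0.97), ILMN_1371357 (0.94), Adora2a (0.83), ILMN_1352355 (0.83), Sgk1 (0.82), ILMN_1366937 (0.77), Dynlt3 (0.76), ILMN_1362029 (0.75), Nnat (0.74), Rxrg (0.74), Lyzl4 (0.73) and Coch (0.72). ILMN_1351707 was at 7.43 to 8.35 in the animals of the 3 dimmest arrays and at 5.94 to 6.14 elsewhere. Nnat (neuronatin, an imprinted gene) was at 9.36 in male 5 and 7.12 to 7.55 in the others, and Rxrg, a retinoid receptor, at 9.07 and 6.74 to 7.90. Nnat had 2 probes, and every Nnat value given is of ILMN_2040120 alone. Over all 18531 tested probes, 6 had a gap of more than 2 log2 units between neighbouring animals: Ttr, ILMN_1365113, Sorbs2, Mrpl18, Rps9 and ILMN_1650254, the last at 10.30 and 9.11 in males 1 and 6 and at 5.73 to 6.07 elsewhere.

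**Figure D4:**
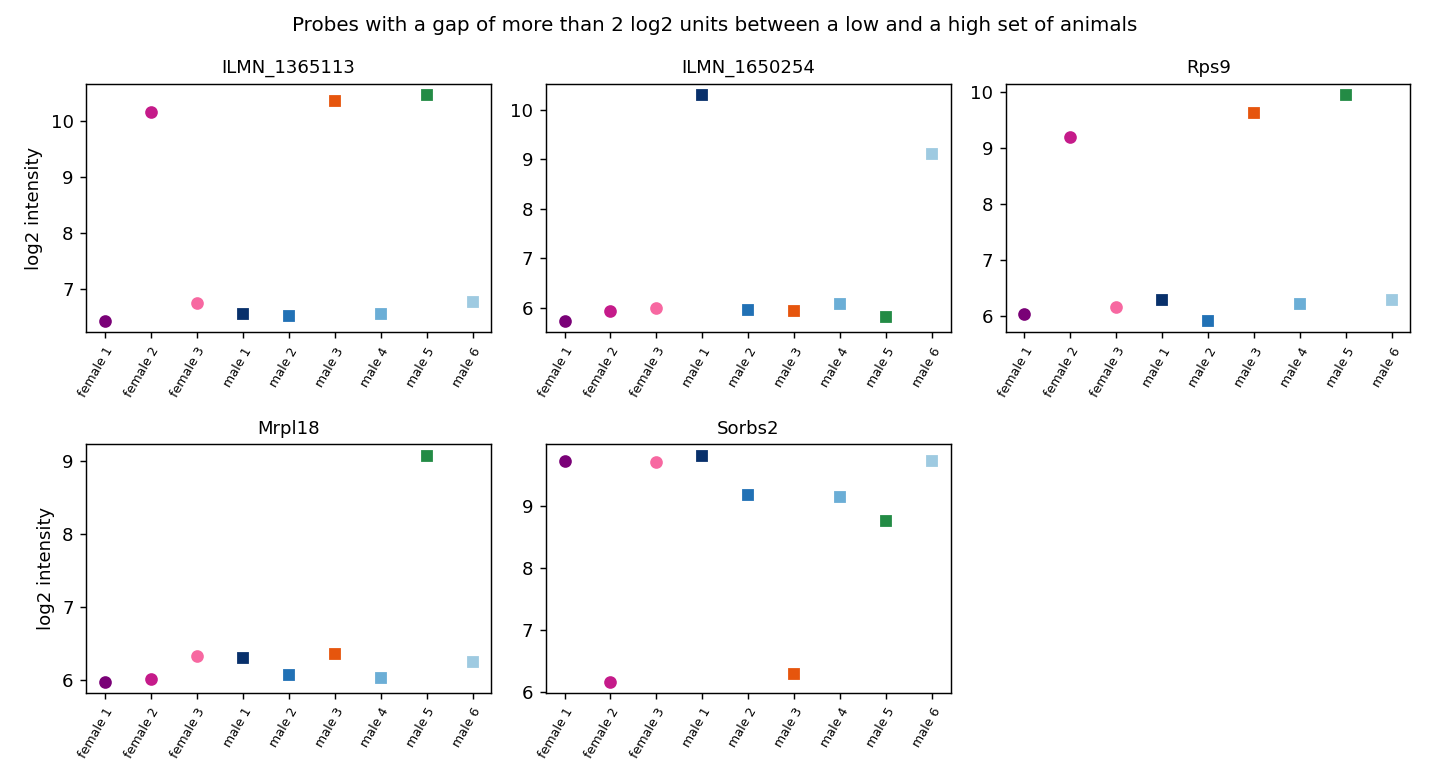
Log2 intensity in each of the 9 animals of the probes, other than Ttr, with a gap of more than 2 log2 units between neighbouring animals, one panel per probe with its own vertical axis. ILMN_1365113 and Rps9 are high in female 2, male 3 and male 5, ILMN_1650254 in males 1 and 6 and Mrpl18 in male 5, and Sorbs2 is low in female 2 and male 3.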

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

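The counts over other splits for single probes at an adjusted p of 0.05 (sexes and title numbers) and at 0.001 were tests chosen only after the result was seen. So were the splits for gene lists with 1 animal per title number and the scaled comparison of male 2 with male 3. Planned tests were changed as well. First, a bootstrap interval, a repeat without single arrays or a 5th percentile was required before an explanation was set aside. Rps9 and ILMN_1650254 were added to the split probes, and Ttr was taken out of them. Last, permuted orders were not used to decide where the high set had too few distinct placements. Without the first change, brightness, white matter and, for ILMN_1650254, tissue makeup would have been set aside by the bounds fixed earlier. Carry-over in male 2 would also have been set aside without that change and the scaled comparison. Ttr, with 11 followers against a permuted median of 14, met the bound for setting tissue makeup aside. Without the last change, Mrpl18, with 123 followers against a permuted 95th percentile of 113, would have met the bound for tissue makeup. Among 79 sets of 6 male values (28 list scores, 50 named probes and array intensity), 10 had an animal whose gap to the nearest male, as a share of the range, exceeded Dixon's 95% critical value; chance flags about 1 in 20 sets, but 6 of the 10 are probes chosen for the largest SD, which favours animals that stand apart, and the sets are not independent, so no count expected by chance is given. Among the males, male 5 was lowest for the myelin score (gap 0.667 of the range), highest for Mrpl18 (0.889) and Nnat (0.821) and lowest for Lyzl4 (0.639). Male 3 was lowest for the score of GABA receptor and chloride transport genes (0.752) and for Sorbs2 (0.698), and highest for ILMN_1371357 (0.672) and ILMN_1366937 (0.650). Male 4 was lowest for ILMN_1375617 (0.688), and male 6 was lowest for Cep76 (0.629).

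Of the 84 splits of the 9 animals into 3 and 6, 81 gave at least the 1 probe found between the sexes at an unadjusted p of 0.001 with limma, so chance cannot be excluded for that count. All 84 reach the 0 adjusted calls by construction (439 probes at an unadjusted p of 0.05), so that count says nothing about chance. The highest of the other splits gave 981 probes at 0.001 and 1733 adjusted calls. The split with 1733 set males 2 and 4 and female 2, the 3 dimmest arrays, against the rest, and a count so far above the real one points to a structure of the samples that is not sex. For the 10 gene lists called between the sexes with camera's preset correlation, 2 of the 84 splits gave as many, the real one included, and the highest other split also gave 10, with male 1, male 6 and female 2 as the small set. That share is under 0.05, but both splits are among the 27 with 1 animal per title number in the small set, and 2 of 27 does not exclude chance when title number is kept balanced. The count was also 0 with an estimated correlation, 0 with fry and 3 without female 2. Across title numbers, all 90 splits with 1 female and 2 males per set reach the 0 adjusted calls by construction (highest other 1101), which again says nothing about chance. For the 1772 probes at an unadjusted p of 0.05, 7 of the 90 gave as many (highest other 3675), so chance cannot be excluded there.

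Ttr was 5.85 log2 units above the median of the other animals in male 3 and 3.58 above it in male 2; between-array normalization was argued against, since without it the excess in male 3 was 6.01. Choroid plexus tissue carried over at dissection may account for male 3: 14 other choroid plexus markers (without F5 and Igf2, seen earlier) lay a median of 0.41 above the other animals, beyond the central 95% of random lists (upper limit 0.056), with Sostdc1 2.57, Enpp2 1.18 and Aqp1 0.73 above the 7 animals other than males 2 and 3; 3 of the 17 measured genes stand in another list, and no sort or gate would have removed such cells. For male 2 the median was 0.051, inside the limit of 0.069, so the bound fixed earlier would set carry-over in male 2 aside. A later comparison scaled the deviations of male 3 by the Ttr excess of male 2, 19.5% of that of male 3. It predicted, against the 7 others, a median of 0.087, above that limit, where 0.068 was observed. Observed minus predicted had a median of -0.0039 (bootstrap interval -0.04 to 0.03). Sostdc1 was at 1.01 where 0.97 was predicted and Enpp2 at 0.31 where 0.32 was. Aqp1 (0.04 where 0.17 was predicted), Igfbp2 (-0.05 and 0.15) and Steap1 (-0.15 and 0.10) fell short. A smaller carry-over in male 2 stays open, since few genes had a predicted change above the spread and these did not all follow. No biological explanation was tested, since both animals share the group of the other males.

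Males 2 and 4 and female 2 lay at 12.4 to 15.2 on the first principal component (33.3% of the variance) and the others at -1.85 or below, and 914 probes were higher and 819 lower in these 3 at an adjusted p of 0.05 (limma), which restates the separation the 3 were grouped by. Array brightness cannot be told apart from other sources: among the 6 brighter arrays, Pearson's r of the component with mean intensity was -0.27 (permutation p = 0.64) and Spearman's rho was -0.029 (permutation p = 1), where brightness needs a negative r; the value meets the bound fixed earlier (absolute r under 0.3) but not by more than its spread, since it was -0.58 without male 6 and 0.58 without male 5. Without the 2 arrays farthest from the median intensity r was 0.67, of the opposite sign, so no relation held within these arrays, and the dim arrays are the same 3 animals that lie apart. More white matter in these samples also stays open, since 19 myelin markers lay a median of 0.088 above the other animals (upper limit of random lists 0.10, bootstrap interval -0.05 to 0.24); against it, the myelin score of male 4 was -0.05, below those of male 1 (-0.0019) and female 3 (0.05), and male 3, which does not lie apart, had the highest (0.23). The 3 animals carry 2 of the title numbers and both sexes, so neither label accounts for all of them, and no biological explanation was tested. Each title also ends in a letter of unstated meaning, J in male 4 and K in male 2 and female 2. Among the other animals only male 1 carries J or K, and it did not lie apart. The letter was not tested, so a source that it may mark stays open.

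The 5 probes other than Ttr with gaps above 2 log2 units were set against a change in tissue makeup and a sequence variant under the probe. A change in tissue makeup should bring many probes that follow with an absolute r of at least 0.9: 123 followed Mrpl18, but with 1 high animal there are only 9 distinct placements, 1 of them male 5 itself, so permuted orders cannot decide, and the count restates that male 5 stands apart. For ILMN_1365113 (26 followers), Rps9 (19) and Sorbs2 (20), counts lay between the median (13 to 14) and the 95th percentile (35 to 43) of permuted orders and decide nothing. ILMN_1650254 had 15, at its median of 15, which meets the bound fixed earlier but lies inside the spread of permuted orders (5th to 95th percentile 6 to 43), and Ttr, weighed apart, had 11 against a median of 14. A sequence variant cannot be told apart from a change in transcript level, because the named genes had 0 second probes. No biological explanation was tested.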

How the results depend on the processing

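Leaving out the 3 dimmest arrays and leaving out males 3 and 5 were tests chosen only after the data were seen. Between the sexes, 0 probes passed an adjusted p of 0.05 under each of 21 alternatives, and the count at an unadjusted p of 0.05 (439 with limma) ranged from 162 with scaling to the 75th percentile to 720 without female 2, with 288 without female 1. The count of 1 at an unadjusted p of 0.001 was 0 without normalization between arrays, 2 with no filter, 4 with array weights, 6 with the per-probe test, 7 without the 3 dimmest arrays and 2 without males 3 and 5. Leaving out single animals gave 0 to 7: 0 without female 1, female 3 or male 5, 2 without male 1, 5 without male 3, 6 without male 2 and 7 without female 2. The 10 gene lists called by camera became 0 with an estimated correlation and 0 with fry, which tests another hypothesis; leaving out single animals gave 3 (without female 2) to 11, and the rest gave 7 to 12. The median of the microglia markers ranged from -0.0017 (without female 2, a reversal) to 0.065 when single animals were left out, and was 0.12 with a floor of 64 and 0.023 with scaling to the 75th percentile. The other called lists kept the sign of their median. Over all 10, 52 list values kept their sign but no longer passed, those of the estimated correlation and fry included. The reversed microglia value without female 2 did not pass either (camera adjusted p = 0.48). With title number as a block, limma called 0 probes and camera 10 lists. Across title numbers the count of 0 became 3 without the 3 dimmest arrays and was 0 to 1 when single animals were left out (1 without male 4). The 10 lists that varied together became 4 without normalization between arrays, were 9 to 11 when single animals were left out and 8 to 12 otherwise; interferon and MHC genes lost their call most often, in 4 settings. Unless stated, the cause was not tested. The normexp alternative was not run because it was the main setting, and single title numbers gave values for the named probes but no test. For arrays, signal over background limits dim probes, which the offset of 50 compresses.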

Other observations

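The genes of male 5 named here were chosen only after their values were seen, except Nnat, Lyzl4, Mobp and Scn4b, which the rule for named genes gives, and no test was run on this choice. In male 5, 100 genes lay at least 0.5 log2 units beyond the range of the other 8 animals, against 18 in male 3, 7 in female 2 and 3 or fewer in each of the rest. Genes farthest above the others included Nnat (9.36 in male 5 and a median of 7.23 in the others), Efnb3, an ephrin ligand (10.80 and 8.91), Hap1, the huntingtin-associated protein gene (9.44 and 7.61), Glra2, a glycine receptor subunit (8.97 and 7.48), Ptpro (10.35 and 8.59), Hrk (8.40 and 6.74), Necab2 (9.38 and 7.85) and Zcchc12 (11.43 and 10.13). Genes farthest below included Lyzl4 (6.76 and 8.67), Mobp (9.20 and 10.67), Tnnc2 (7.97 and 9.26), Lamp5 (10.67 and 11.91), Scn4b (7.11 and 8.58), Cyp11b1 (7.71 and 8.84) and Olr59 (7.45 and 8.53). These are values of 1 animal with no replicate.

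Haemoglobin transcripts, a sign of blood left in the tissue, averaged 11.46 ± 0.34 (SD, n = 3) in females and 11.99 ± 0.30 (SD, n = 6) in males for Hba-a1, and 10.93 ± 0.58 and 11.46 ± 0.39 for Hbb, on the log2 scale. The blood list did not vary together beyond random lists (adjusted p = 0.15, random-list test). Hippocampal markers, which the dissection should have kept low, did not pass either (adjusted p = 0.71, random-list test), but male 5 had the highest hippocampal score, 0.18 against -0.09 to 0.04 in the other 8 animals. The test asks whether genes vary together, and the score is a deviation from the median of all animals. Neither measures the level of these markers, so hippocampal tissue present alike in every sample would not show. Wfs1 had an SD within sex of 0.41 and was highest in male 5, with 6.60 to 7.32 in the others.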
